A study of Mus musculus with 8 samples.

How the data were processed

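Gene expression was measured in single cells of the mouse heart ventricle (ICR/CD1, an outbred strain) with the 10x Genomics Single Cell 3' v2 droplet assay. Per the labels' protocols, mice had myocardial infarction (MI), made by tying off the left anterior descending coronary artery for good, or a sham operation at postnatal day 1 (P1) or 8 (P8). Tissue below the level of the ligation was digested to single cells 1 or 3 days later, and the matching region was taken from sham hearts. The 8 samples are 8 libraries, 1 for each combination of age, surgery and day, and the labels put each in its group. How many pups or what sexes went into a library is not given in the sources used here.

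Each sample came as a deposited matrix of UMI counts, whole numbers of distinct molecules per gene and cell barcode, with no normalization. Per the submitters' processing notes, Cell Ranger and Seurat were used with the mm10 (GRCm38) mouse genome. Their versions, and how cell barcodes were told from empty droplets, are not given in the sources used here. The library of P8 MI day 1 listed 27998 genes and the other 7 listed 28692. The 27998 genes shared by all were kept, and the other genes held between 0 and 0.0427% of a library's counts. No cell annotation of the authors was used here, so cell classes were rebuilt. Empty droplets were not analysed here.

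Barcodes with at least 500 detected genes and at most 20% mitochondrial UMIs were kept, 17459 of 18862. Doublets were taken per library as the barcodes with the highest share of simulated doublets (2 simulated per barcode) among their nearest neighbours, at 0.8% per 1000 barcodes. That marked 2.12% of all barcodes, removed 383 of those that passed the limits above and left 17076 cells. All 17459 barcodes within the limits, marked doublets included, were clustered together without batch integration. This used 2000 variable genes, 30 principal components and 15 neighbours (Leiden, resolution 1) and gave 33 clusters. The doublets were taken out of the clusters afterwards. A cluster took the class whose markers had the highest mean log2 fold (50 CPM added), from 17 marker lists, with the macrophage and monocyte lists counted together. The top 10 genes of the cluster by fold could only take that name away. CPM are counts scaled to a common total per library and class. It stayed unnamed with under 20 cells, with fewer than 3 detected markers, with none of its own markers among those 10 genes or as many or more of another class, or where the gene with the largest fold was a marker of another class only. Endocardial clusters could share these places with endothelial markers, and a B cell cluster could be led by an antigen presentation gene of dendritic cells, so that 1 cluster of each was named. All class names below therefore mean X-like clusters, such as fibroblast-like. 30 clusters were named, and 3 with 296 cells (1.73%) were not.

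The counts of a class were summed per library. Classes with at least 20 cells in every library were eligible, and the 4 with the largest smallest number of cells were tested: endothelial (at least 266 cells per library), mural (177), fibroblast (121), and monocyte or macrophage (35). Sums were tested with edgeR's quasi-likelihood test after TMM normalization and filterByExpr. CPM of genes given with these tests include the TMM factors. CPM of marker sums, single settings, untested classes and the genes that set P8 MI day 1 apart do not. The same gene can therefore have different CPM in different places. Surgery, age and day were additive terms with 4 residual degrees of freedom, and age by surgery and day by surgery terms were tested with 3. The P values were adjusted by Benjamini-Hochberg within a class and term, with a threshold of 0.05. Since each condition has 1 library, the spread behind every p-value is that between libraries of different age and day, part of which may be technical. Numbers of cells per class were tested with edgeR in the same way, with an exact sign-flip test over the 4 MI and sham pairs beside it, whose smallest two-sided p is 0.125. Shares have exact Clopper-Pearson 95% intervals and single-library sums exact Poisson 95% intervals. Both cover counting error only. For a count of 0 a fold is given as a lower bound against 3 counts in that library.

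19 gene lists were tested with camera at a preset correlation of 0.01, adjusted over all lists and classes, and again with an estimated correlation. The gene lists, cell markers, designs and alternatives were fixed before the data were examined. For MI, the named genes were up to 6 higher and 6 lower per class with the largest change among those past the test, with a mean of at least 20 CPM and 1 direction in all 4 pairs. Up to 4 members of each gene list past the test were added. For age the same rule was used without the pair condition. For the interactions, the named genes were up to 5 per direction, or the 5 with the smallest p where fewer than 5 passed. Clcf1, Rspo1, Igf1, Igf2, Postn, Arg1, Spp1 and Lyve1 were always named at 5 CPM or more, which Rspo1 reached in no tested class. In single settings, where there is no test, up to 5 genes per direction were named by ratio with 10 CPM added and at least 30 counts in 1 of the libraries. In untested classes, up to 3 list members per direction were named. Xist, Tsix and Y-linked genes were left out of this rule because the sexes in a library can differ. A few genes that the rule names are not reported here.

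RNA of other cells (free RNA) was estimated without empty droplets. In each class, the counts of other classes' markers were divided by those that the library's own summed profile would give, and the median of 18 such values was taken per library. A gene's expected free RNA is that share times the library profile. As an alternative chosen after seeing the data, the expected counts were subtracted and every test was repeated. Fits on P1 or P8 libraries alone, fits with an unnamed cluster of mixed endothelial and mural genes added to endothelial cells, and fits without a mural cluster of P8 MI day 1 were also chosen after seeing the data. Other alternatives were DESeq2, RLE factors, no count filter, a limit of 10% mitochondrial UMIs, no doublet removal, thinned sums, leaving out each MI and sham pair, other designs and Leiden resolution 0.5. The fits were tested on simulated counts with 200 changed genes. These were drawn at the depths of the libraries with the trended dispersion and no effect besides the tested one. They hold no free RNA, so the share of changes found in the real libraries may be lower.

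The software was R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9. Gene positions are from the GENCODE vM21 annotation of GRCm38, matched by Ensembl gene ID. Depth limits the precision unevenly. The summed counts behind a tested library ran from 1217916 to 8662622 in endothelial cells, 611103 to 1405842 in mural cells, 540546 to 11489939 in fibroblasts and 217066 to 6675532 in monocytes or macrophages.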

Results

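The data set has 8 single-cell libraries of neonatal mouse ventricle, 1 each for MI and sham surgery at P1 or P8 and collection 1 or 3 days later. The series compares a heart operated at P1, an age at which the mouse heart regenerates, with a heart operated at P8, when that ability has been lost. Total UMI counts per library were 30015785 (P1 MI day 1), 19856904 (P1 sham day 1), 31176495 (P1 MI day 3), 16282672 (P1 sham day 3), 6194494 (P8 MI day 1), 9073995 (P8 sham day 1), 13723246 (P8 MI day 3) and 3502948 (P8 sham day 3). The cells used numbered 2272, 2736, 3422, 2724, 1233, 1816, 1705 and 1168 in the same order. Median UMIs per barcode ran from 1557 in P8 sham day 3 to 10189.5 in P1 MI day 1. Median mitochondrial shares ran from 3.01% in P1 MI day 1 to 10.1% in P8 sham day 1. The estimated share of free RNA was 31.2% in P1 MI day 1 and 27.0% in P1 MI day 3, against 8.58% and 4.33% in their shams. At P8 it was 4.82% (day 1) and 5.11% (day 3) after MI, against 15.3% and 10.2% in sham. Clusters drawn to at least 90% from 1 library held 52.6% of the cells of P1 MI day 1, 56.4% of P1 MI day 3 and 3.65% of P8 MI day 1.

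**Figure D1:**
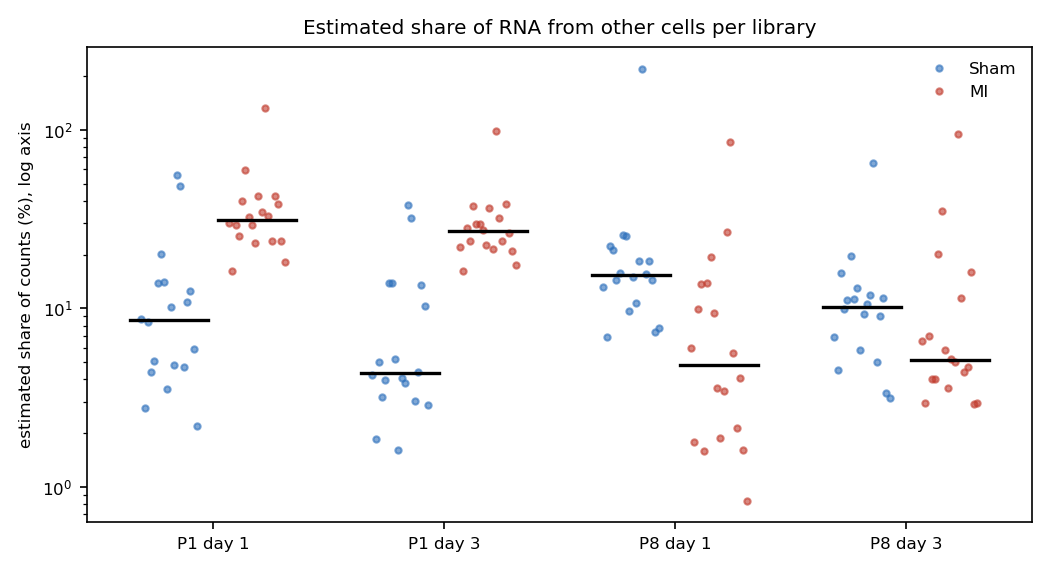
Estimated free RNA per library, in percent of a library's own summed profile on a log axis. Each point is 1 of 18 estimates, from 1 class and 1 marker list of other cells, and the bar is their median, highest in P1 MI day 1 (31.2%) and P1 MI day 3 (27.0%).

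The first question is which cell classes became more or less frequent after MI. Monocytes or macrophages, the phagocytes of the infarct, had a higher share after MI in all 4 pairs and rose 2.95-fold (log2 1.56 ± 0.52 SE, adjusted p = 0.0439, edgeR). Their share was 24.6% (95% interval 22.9 to 26.5) in P1 MI day 1 against 4.71% (3.95 to 5.58) in its sham. On P1 day 3 it was 14.5% against 5.95%, on P8 day 1 3.33% against 2.37%, and on P8 day 3 9.21% against 3.00%. Dendritic cells, which present antigen, rose 6.15-fold (log2 2.62 ± 0.64 SE, adjusted p = 0.016), with 18, 17, 5 and 27 cells in the MI libraries against 3, 3, 2 and 2 in sham. Epicardial cells, from the outer layer of the heart, rose 6.30-fold (log2 2.65 ± 0.77 SE, adjusted p = 0.0259), most on P8 day 3, where they were 7.16% (5.98 to 8.48) of cells against 0.257% (0.0530 to 0.749).

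Endothelial cells had a lower share after MI in all 4 pairs, 11.7% against 36.7% on P1 day 1 and 30.9% against 52.8% on P8 day 3, but the change did not pass (log2 -0.68 ± 0.49 SE, adjusted p = 0.371). B cells were also lower in all 4 pairs (log2 -1.58 ± 0.64 SE, adjusted p = 0.0873) and endocardial cells higher in all 4 (log2 0.88 ± 0.49 SE, adjusted p = 0.229). Fibroblasts were 33.4% of cells in P8 MI day 3 against 10.4% in sham, and close to their sham in the P1 pairs (36.8% against 38.4% and 39.5% against 36.4%; adjusted p = 0.609). Neutrophil shares were above sham on day 1 (4.14% against 1.39% at P1, 5.27% against 1.21% at P8) and below it on day 3 (0.906% against 1.69%, 1.88% against 3.85%), with an adjusted p of 0.657 over the 4 pairs. Cardiomyocytes (log2 0.47), mural cells (-0.39), erythroid cells (-0.03) and unnamed cells (-0.33) did not pass either. The exact sign-flip p of each class that moved in 1 direction in all pairs was the smallest that 4 pairs allow. Shares are of the cells that survived digestion, and monocytes or macrophages lost the call with TMM factors on the class counts (log2 1.49) and with at most 10% mitochondrial UMIs (1.39), as epicardial cells did (2.60 and 2.72) and dendritic cells did with the mitochondrial limit (2.36). Each call rested on several pairs. Without the P1 day 1, P1 day 3, P8 day 1 or P8 day 3 pair the adjusted p was 0.36, 0.208, 0.0377 and 0.15 for monocytes or macrophages, 0.0788, 0.065, 0.0258 and 0.0572 for dendritic cells, and 0.077, 0.053, 0.0797 and 0.0572 for epicardial cells, whose change without P8 day 3 was 1.68.

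**Figure D2:**
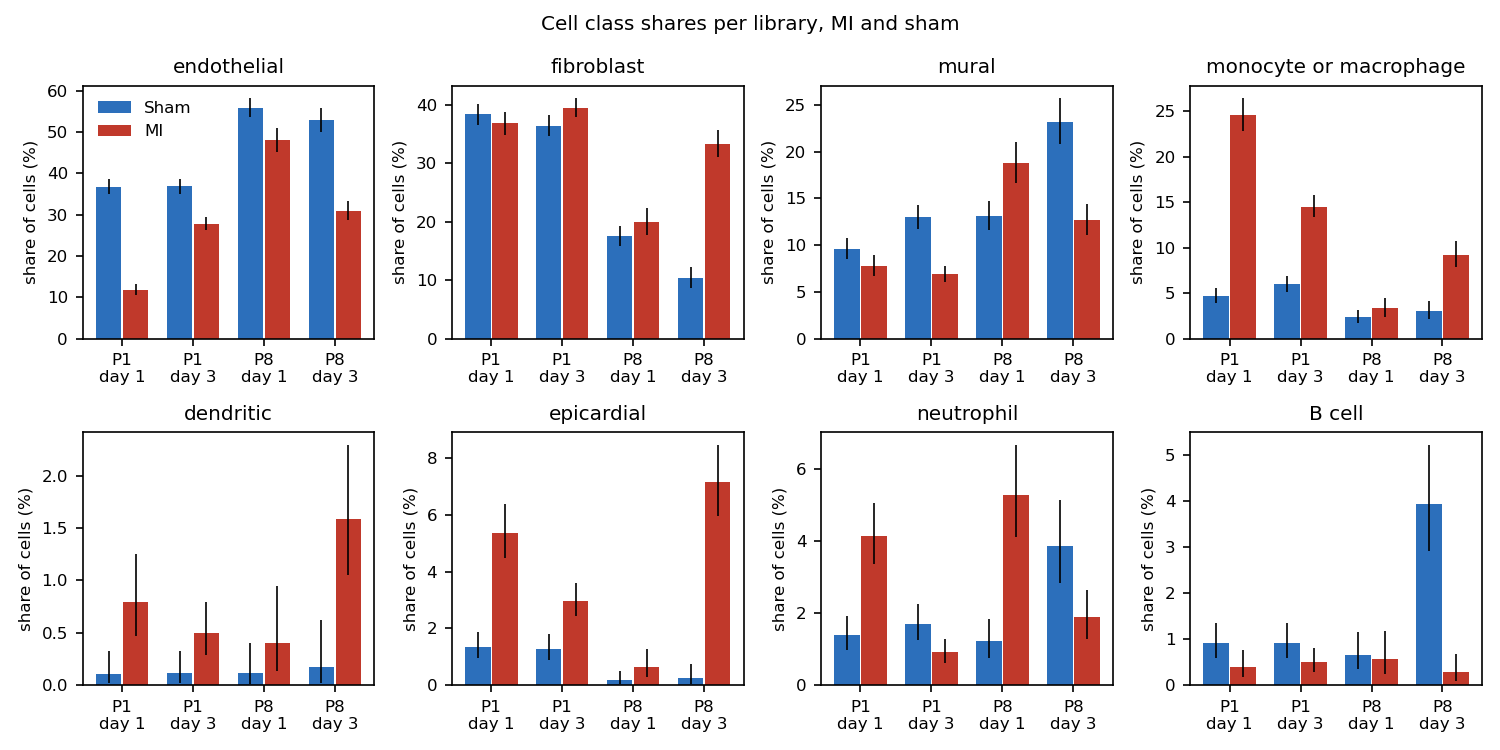
Share of 8 cell classes among the cells of each library, in percent. Bars are shares, blue for sham and red for MI, and lines are exact 95% binomial intervals, which cover counting error only. The share of monocytes or macrophages is above sham in all 4 pairs, from 3.33% against 2.37% on P8 day 1 to 24.6% against 4.71% on P1 day 1.

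The next comparison asks which genes of fibroblasts changed with MI over both ages and days. Contractile genes rose as a list (adjusted p = 0.458 with an estimated correlation), and single matrix genes rose or fell. Col8a1, a short-chain collagen of remodelling vessels and scars, rose 4.87-fold (log2 2.29 ± 0.20 SE, 4 pairs, adjusted p = 0.00455), from 15.2, 18.8, 52.1 and 104 CPM in sham to 78.1, 75.3, 333 and 448 CPM after MI (P1 days 1 and 3, then P8 days 1 and 3). Timp1, an inhibitor of matrix metalloproteinases, rose 4.62-fold (2.21 ± 0.26, adjusted p = 0.0121) and reached 3933 CPM in P8 MI day 1 against 675 CPM in sham. Wisp2, a CCN family matricellular protein, rose 5.84-fold (2.55 ± 0.39, adjusted p = 0.0226), and Tagln, an actin-binding protein of smooth muscle and myofibroblasts, 5.25-fold (2.39 ± 0.40, adjusted p = 0.0291). Clec3b, a plasminogen-binding secreted protein, fell to 0.288 of sham (-1.79 ± 0.23, adjusted p = 0.0137), with 109, 136, 177 and 105 CPM after MI against 324, 395, 607 and 542 CPM.

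Of 13078 genes tested in fibroblasts, 117 were higher and 47 lower after MI (edgeR, Benjamini-Hochberg). The lower ones include the Y-linked Ddx3y, Uty and Eif2s3y. In the contractile and myofibroblast list, 5 of 12 members rose with adjustment over all genes and 9 adjusted over the list alone, and all 12 were above sham on average. Besides Tagln these were Actg2 (log2 2.31 ± 0.33), Acta2 (1.66 ± 0.30), the marker actin of myofibroblasts, Tpm2 (1.14 ± 0.17) and Cnn2 (1.02 ± 0.20, named after its value was seen), and the median of the list was 0.97 (camera adjusted p = 5.18e-11). That call was lost with an estimated correlation (adjusted p = 0.458 with an estimated correlation). The sum of 11 mural markers in fibroblasts was higher after MI in all 4 pairs (1841 against 667, 1300 against 638, 799 against 525 and 2570 against 734 CPM), and 2 of them, Acta2 and Tagln, are members of this list. The other 9 markers had 175 against 268, 241 against 240, 149 against 252 and 150 against 222 CPM. Extracellular matrix genes went both ways, 5 higher and 5 lower adjusted over the list alone, with Col8a1 and Timp1 up and Lum (-0.95 ± 0.19) down, and the list had an adjusted p of 0.398. Also higher were Adamtsl2 (2.34 ± 0.43), a matrix protein that binds fibrillin, and Meox1 (1.71 ± 0.25), a homeobox factor of activated fibroblasts. Lower were Nov (-1.85 ± 0.29), Gdf10 (-1.82 ± 0.21), Col6a6 (-1.73 ± 0.24), Anpep (-1.56 ± 0.21) and Scara5 (-1.62 ± 0.32). Different clusters held most fibroblasts: cluster 5 in P1 MI day 1 (98.0%), cluster 3 in P1 MI day 3 (83.8%), cluster 10 in the P8 MI libraries and cluster 1 in the shams.

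Glycolytic and proliferative lists rose in fibroblasts as well. For hypoxia and glycolysis, 4 of 22 members passed over all genes and 10 adjusted over the list alone, with a median of 0.68 (adjusted p = 2.74e-06; 0.566 with an estimated correlation). The 4 were Mif (1.31 ± 0.24) and the glycolytic enzymes Pfkl (1.27 ± 0.24), Tpi1 (1.17 ± 0.20) and Ldha (1.02 ± 0.20). Of 24 cell cycle genes, 0 passed over all genes by edgeR (2510 genes of the class had an unadjusted p under 0.05, and DESeq2 called 569), 10 passed adjusted over the list alone and 22 were above sham, with a median of 0.63 (adjusted p = 6.89e-07; 0.566 with an estimated correlation). The fetal and imprinted list fell, with 2 of 17 members passing over all genes and 4 adjusted over the list alone, median -0.58 (adjusted p = 1.88e-05; 0.458 with an estimated correlation). Its called members were Zim1 (-2.10 ± 0.32) and Meg3 (-0.86 ± 0.17), both imprinted genes. Igf2 in the same list had -0.79 (adjusted p = 0.174), and outside it Igf1 had 0.36 (0.243), Postn -0.46 (0.242) and Clcf1 0.60 (0.409).

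Macrophage genes moved in fibroblast sums together with free RNA. Il1a (log2 6.21), Msr1 (6.19), Trem2 (5.89), Ccl24 (5.06), C3ar1 (4.48) and C1qc (3.99) passed the test, and the free RNA estimate gave at least as many counts as were seen. For Il10 (5.29) and Il1rn (4.13) it gave 90.3% and 90.2%, for Ccl3 (3.40; adjusted p = 0.036 after subtraction) 88.7% and for the endothelial gene Plvap (1.89) 77.5%. Csf3 (4.63; 82.4%) and Areg (3.48; 100%) stood likewise, and Ereg (2.72 ± 0.54), an epidermal growth factor ligand, had 24.4%. Of the 117 higher genes, 53 had at least 50% free RNA in their highest library and 23 still passed after subtraction, as did 14 of the 47 lower genes, with the Y-linked Ddx3y and Eif2s3y among these 14. Spp1 (3.96, adjusted p = 0.0771) and Arg1 (5.62, 0.0518) did not pass and had 100%. The lists for cytokines and chemokines (adjusted p = 1.04e-05), interferon response (0.0143), phagocytic macrophages (0.00386), alternative activation (0.00476) and antigen presentation (0.0233) were up, and none of these calls held with an estimated correlation (adjusted p = 0.566 and, for antigen presentation, 0.627 with an estimated correlation). After subtraction 4 of them had 0.902, 0.477, 0.653 and, for antigen presentation, 0.203, and alternative activation had too few members left. On P8 day 3 the medians were -0.46 (cytokines), 0.13 (interferon), -0.30, -0.78 and -0.41, against 3.41, 0.82, 1.04, 3.28 and 1.34 on P1 day 1. Without the P1 day 1 pair they had 0.122, 0.22, 0.482, 0.897 and 0.485, and without P1 day 3 the last 4 had 0.176, 0.572, 0.795 and 0.412. Col8a1 (adjusted p = 0.00512), Timp1 (0.0301), Wisp2 (0.0348), Actg2 (0.0241), Acta2 (0.036), Tpm2 (0.032), Clec3b (0.0347) and Gdf10 (0.0241) still passed after subtraction. Tagln (0.0522), Adamtsl2 (0.0616), Scara5 (0.103), Lum (0.108), Meg3 (0.107) and the 4 glycolytic genes (0.0522 to 0.0651) did not. With the P1 day 1 or the P1 day 3 pair left out, 0 genes passed by edgeR in fibroblasts, and 7 did without P8 day 3 and 389 without P8 day 1. P1 libraries alone gave 1389 and P8 libraries alone 0. These fits have fewer libraries and few degrees of freedom, so the gap between the counts does not measure an age difference. With each age and day as a block, and so each pair, 87 fibroblast genes passed (62 higher, 25 lower). The calls lost there included those of Scara5 (adjusted p = 0.065), Lum and Ldha (0.0598), Tpi1 (0.0518), Meg3 (0.0579), Ccl3 (0.065), Il10 (0.0598) and Ereg (0.0533), while Col8a1 (0.0119), Timp1 (0.0225), Tagln (0.0214), Acta2 (0.017) and Clec3b (0.0162) passed.

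In endothelial cells, 5 genes were higher and 3 lower after MI, of 11927 tested (edgeR), the lower ones with the Y-linked Ddx3y among them (adjusted p = 0.0486). Capg, an actin filament capping protein, rose 2.89-fold (log2 1.53 ± 0.16 SE, 4 pairs, adjusted p = 0.0467), with 184, 98.3, 97.0 and 79.4 CPM after MI against 54.1, 35.8, 43.6 and 23.8 CPM in sham (P1 days 1 and 3, then P8). Tubb6, a beta tubulin, rose 2.33-fold (1.22 ± 0.14, adjusted p = 0.0467). Yes1, a Src family kinase (-1.34 ± 0.16), and Kansl1l (-1.10 ± 0.14) fell. Aebp1 (1.55 ± 0.19), known from matrix-producing cells, passed with 68.9% free RNA and had an adjusted p of 0.504 after subtraction, while Capg, Tubb6 and Kansl1l had 0.0422 and Yes1 0.0545. Igf1 (-0.64 ± 0.16), Igf2 (-0.21, adjusted p = 0.568) and Postn (0.76, 0.436) did not pass, nor did Spp1 (3.47, 0.225) and Arg1 (adjusted p = 0.233), both at 100% free RNA. Leaving out any 1 pair left 0 genes (edgeR; the full fit had 2208 with an unadjusted p under 0.05 and DESeq2 called 198), and 0 passed at Leiden resolution 0.5, with thinned sums or with the stricter mitochondrial limit. With each age and day as a block 1 gene passed, and Capg (adjusted p = 0.0829), Tubb6 and Yes1 (0.0832), Aebp1 (0.089) and Kansl1l (0.0984) did not. Cluster 21 held 89.8% of endothelial cells in P1 MI day 1 and cluster 6 83.7% in P1 MI day 3, and cluster 0 or 2 was the largest elsewhere, with 28.3% (P8 MI day 3) to 64.7% (P8 sham day 3).

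Cell cycle genes rose in endothelial cells as a list, with a median of 0.48, 23 of 24 above sham and 1 passing adjusted over the list alone (adjusted p = 3.34e-06; 0.566 with an estimated correlation). Their median was -0.21 in the P1 day 1 pair and 0.62, 0.68 and 0.81 in the others. Hypoxia and glycolysis genes had a median of 0.45 with 5 of 22 passing adjusted over the list alone (adjusted p = 0.000227; 0.566 with an estimated correlation), and contractile genes a median of 0.51 (0.0238; 0.566 with an estimated correlation). These 3 lists kept their call after free RNA was subtracted, and contractile genes lost it without the P1 day 1 (0.213) or the P1 day 3 pair (0.176). The median of contractile genes was 1.41 and 1.35 in the P1 pairs and -0.20 and -0.57 in the P8 pairs (days 1 and 3), and mural markers in endothelial cells had 414, 289, 179 and 176 CPM after MI against 105, 71.8, 374 and 431 CPM in sham. Those for extracellular matrix (6.89e-07, median 0.72), cytokines (0.000708, 1.29), phagocytic macrophages (0.000248, 0.85) and complement (0.00528, 1.99) rose too, each with an adjusted p of 0.566 with an estimated correlation. After subtraction the first 3 did not pass (0.517, 0.655 and 0.572) and complement had too few members left, and without the P1 day 1 pair cytokines (0.213), phagocytic genes (0.0702) and complement (0.233) did not, nor complement without P1 day 3 (0.279). The medians of matrix genes were 1.51, 0.90, -0.43 and 0.42 those of cytokines 3.02, 1.04, -0.95 and 0.14, and those of complement 3.36, 2.69, -1.06 and -0.79. Fibroblast markers in endothelial cells had 1327, 1698, 138 and 563 CPM after MI against 403, 293, 416 and 523 CPM, and macrophage markers 1204, 2210.3, 71.5 and 183 against 131, 137, 154 and 299.7 CPM. By the fibroblast markers alone the free RNA share was 16.2% and 16.1% in P1 MI days 1 and 3. There 31.2% and 27.0% were subtracted, which may be too much for matrix genes. The lists for angiogenic and tip cell genes (adjusted p = 0.0556), capillary fatty acid handling (0.347), endothelial activation (0.136), secreted factors (0.308), interferon response (0.094) and antigen presentation (0.648) did not pass.

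Mural cells, the pericytes and smooth muscle of vessels, had 18 genes higher and 22 lower of 9225 tested. The lower ones include the Y-linked Ddx3y and Uty. Tfpi2, a protease inhibitor, rose 7.25-fold (log2 2.86 ± 0.43 SE, 4 pairs, adjusted p = 0.0283), with 101, 10.7, 133 and 23.3 CPM after MI against 13, 5.29, 6.51 and 3.40 CPM in sham. Nupr1, a stress-induced chromatin protein, rose (1.94 ± 0.23, adjusted p = 0.0283), and so did Timp1 (2.98 ± 0.36), S100a4 (2.30 ± 0.34) and Capg (1.67 ± 0.22). Homer1 (-1.83 ± 0.23), a synaptic scaffold protein, Jmy (-1.76 ± 0.22), an actin nucleator, Reln (-1.69 ± 0.24), Efna2 (-1.58 ± 0.24) and Mamdc2 (-1.58 ± 0.26) fell, as did the haemoglobin gene Hba-a2 (-2.57 ± 0.34). After subtraction Tfpi2, Nupr1 and Jmy (each adjusted p = 0.0488) and Homer1 (0.0371) passed, and Timp1 (0.168), S100a4 (0.244), Pf4 (1.68; 0.15), Ctsb (1.38; 0.191), Capg and Hba-a2 (0.0618), Reln and Efna2 (0.0568) and Mamdc2 (0.0922) did not. Trem2 (5.77) and Aldh1a2 (2.49), of macrophages and epicardium, passed at 100% free RNA. Spp1 (4.27, adjusted p = 0.0691), Igf1 (-0.04, 0.982), Igf2 (-0.48, 0.481), Lyve1 (-0.59, 0.563) and Postn (0.26, 0.79) did not pass. Without the P1 day 1, the P1 day 3 or the P8 day 3 pair, 0 genes passed in mural cells (edgeR; 1620 had an unadjusted p under 0.05 in the full fit and DESeq2 called 161), and 58 did without P8 day 1. With each age and day as a block 12 passed (5 higher, 7 lower), with Timp1 (adjusted p = 0.0468) and with Nupr1, Pf4, Capg, Homer1, Jmy and Reln (0.0496), but without Tfpi2 (0.0676), S100a4 and Efna2 (0.0669), Hba-a2 (0.0554) and Mamdc2 (0.0762). Cluster 26 held 76.8% of mural cells in P1 MI day 1, and cluster 7 or 8 was the largest elsewhere, with 36.8% to 63.0%. Cluster 31, with 45 of its 46 cells from P8 MI day 1, held 19.5% of the mural cells of that library and had Pi15, Clu and Timp1 among its top genes. Without it 9 genes were higher and 16 lower, and Timp1 (log2 2.69, adjusted p = 0.0596), Nupr1 (1.63, 0.0864), S100a4 (2.19, 0.0668), Ctsb (0.107) and Mamdc2 (0.0692) did not pass.

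The mural lists for extracellular matrix (median 0.55, adjusted p = 2.68e-06), phagocytic macrophages (0.84, 6.89e-07), hypoxia and glycolysis (0.29, 0.00253), cell cycle (0.23, 0.0403), cytokines (1.43, 1.8e-06) and antigen presentation (0.65, 0.031) rose. All were lost with an estimated correlation (adjusted p = 0.566, and for cell cycle 0.627, with an estimated correlation), and after subtraction the last 2 were lost (0.888 and 0.86). Antigen presentation was also lost without the P1 day 1 (0.568) or P1 day 3 pair (0.176), cell cycle without P1 day 3 (0.175) or P8 day 3 (0.601), and hypoxia and glycolysis without P1 day 1 (0.0684) or P8 day 1 (0.1). Medians below sham were those of cell cycle (-0.41), cytokines (-0.17) and antigen presentation (-0.28) on P8 day 1 and of hypoxia and glycolysis (-0.21) on P1 day 3. Adjusted over the list alone, 4 matrix genes were higher and 1 lower of 28, 9 and 1 of 18 phagocytic genes, 5 of 22 hypoxia genes, 7 of 14 cytokines and 0 of 24 cell cycle genes. Over all genes 1 matrix gene (Timp1) and 2 phagocytic genes (Trem2, Ctsb) passed. The 10 fibroblast markers in mural cells, 6 of them members of the matrix list, had 2660, 3144, 1485 and 6760 CPM after MI against 2964, 2193, 1558 and 1304 CPM in sham. The other 4 had 172, 268, 16.6 and 143 CPM against 89.1, 74.1, 46.4 and 67.1 CPM. By the fibroblast markers alone the free RNA share of mural cells was 35.3% in P8 MI day 3 and 11.2% in its sham, where 5.11% and 10.2% were subtracted. Macrophage markers in mural cells had 1212, 2145, 67.5 and 152 CPM after MI against 219.6, 141, 177 and 247 CPM in sham.

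Monocytes or macrophages had 6 genes higher and 1 lower of 7966 tested. Hpgd, the enzyme that inactivates prostaglandin E2, fell to 0.212 of sham (log2 -2.24 ± 0.32 SE, 4 pairs, adjusted p = 0.0493), with 15.2, 15.5, 8.08 and 22.5 CPM after MI against 55.3, 122, 30.4 and 110 CPM in sham. It passed after free RNA was subtracted (adjusted p = 0.0237). The resident macrophage list fell, with all 12 members below sham, 4 passing adjusted over the list alone and a median of -0.71 (adjusted p = 0.000115; 0.458 with an estimated correlation; 0.000617 after subtraction). Hypoxia and glycolysis genes rose, 19 of 21 above sham, 11 passing adjusted over the list alone and a median of 0.79 (adjusted p = 2.49e-09; 0.464 with an estimated correlation; 4.04e-13 after subtraction). No member of either list passed over all genes by edgeR (813 genes of the class had an unadjusted p under 0.05 and DESeq2 called 46).

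The higher genes of this class carried more free RNA. Timp1 (3.67 ± 0.53) had 86.9%, Dmkn (3.52 ± 0.43) 64.8%, H2-Eb1 (3.53 ± 0.44), a class II antigen presentation gene, 55.2% and Nppa (3.69 ± 0.54), the atrial natriuretic peptide of cardiomyocytes, 49.5%, and none of the 6 higher genes passed after subtraction. Extracellular matrix genes (median 1.33, adjusted p = 6.88e-12, 13 of 25 passing adjusted over the list alone; 0.00997 after subtraction) and epicardial genes (2.10, 0.00409) were up, both lost with an estimated correlation (adjusted p = 0.566 with an estimated correlation). Their medians were 2.27 and 2.33 on P1 day 1, 2.06 and 1.61 on P1 day 3, -1.47 and -1.86 on P8 day 1 and 0.50 and -0.60 on P8 day 3. Fibroblast markers in this class had 1483, 1854, 64.0 and 561 CPM after MI against 320.4, 449, 469 and 364 CPM in sham. Arg1, the arginase of repair macrophages, was above sham in all 4 pairs without passing (1.90 ± 0.58, adjusted p = 0.297), at 1523, 252, 2189 and 593 CPM against 210, 17.9, 768 and 525 CPM. Spp1 (1.51 ± 1.24, 0.711), Igf1 (-0.43, 0.832), Lyve1 (-0.42, 0.816), Postn (1.05, 0.528), Clcf1 (0.33, 0.812) and Igf2 (0.12, 0.98) did not pass. Without either P1 pair or the P8 day 3 pair, 0 genes passed, and 39 did without P8 day 1. Cluster 11 held 90.4% of this class in P1 MI day 1 and 51.2% in P8 MI day 1, and cluster 4 was the largest in the other libraries (48.8% in P8 sham day 1). The lists for cell cycle (adjusted p = 0.531), cytokines (0.347), interferon response (0.0538), phagocytic macrophages (0.58), alternative activation (0.238) and antigen presentation (0.58) did not pass in it.

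**Figure D3:**
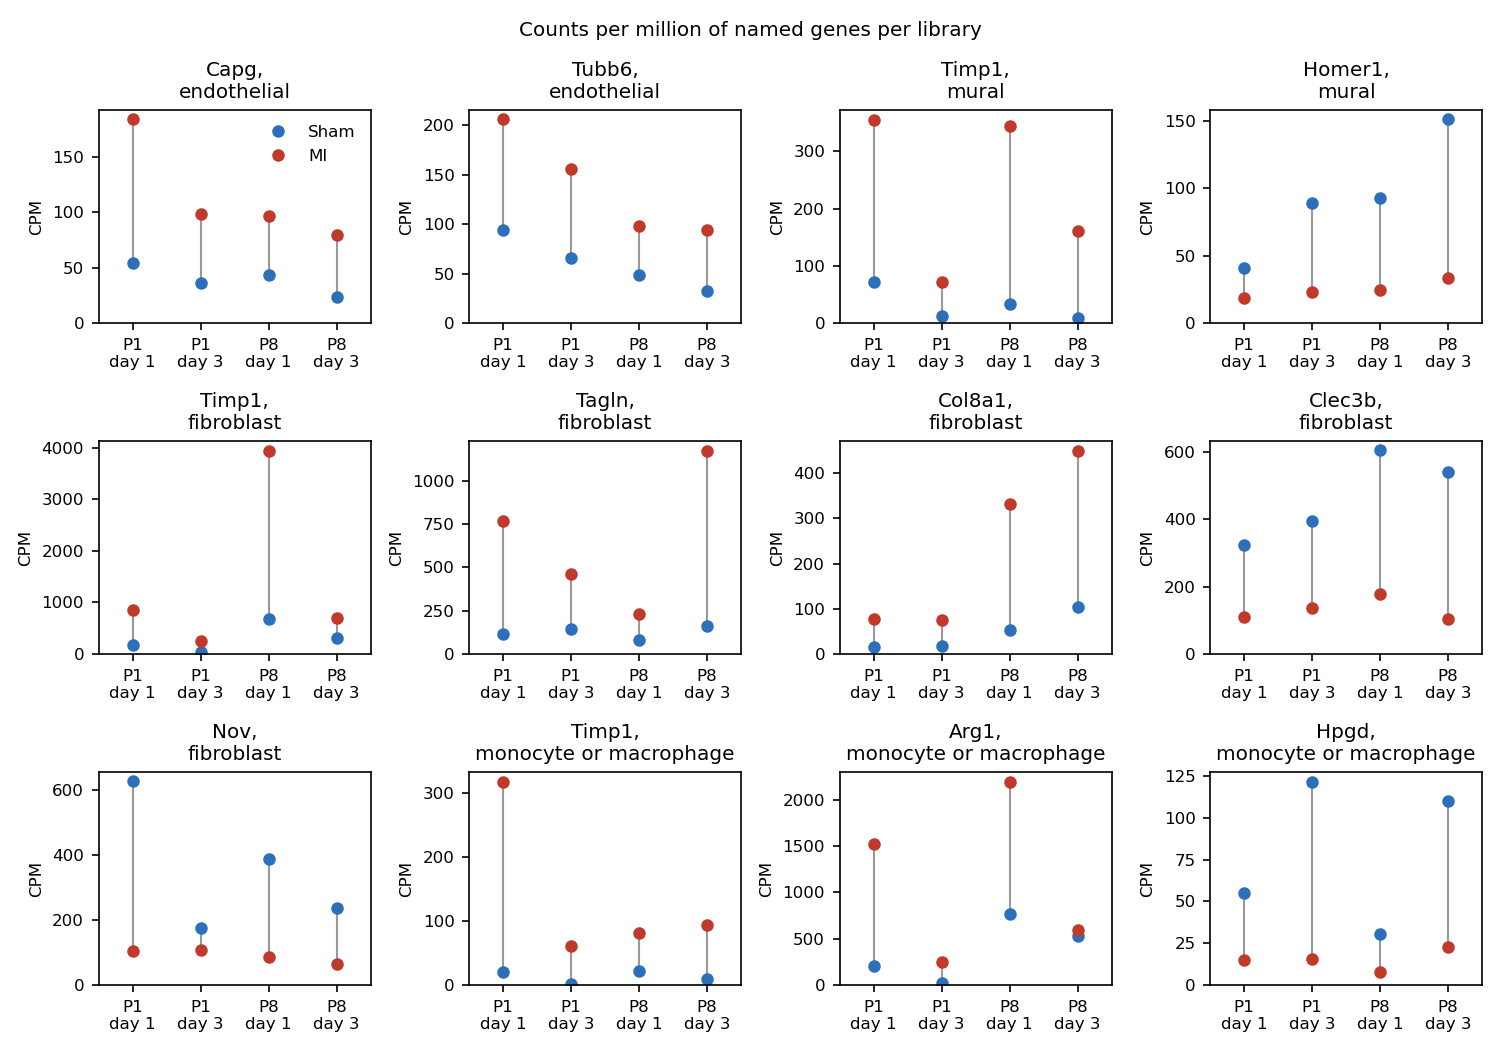
Expression of named genes in the 8 libraries, in CPM, with 1 panel per gene and class, 1 point per library (blue sham, red MI) and a line joining each pair. Fibroblast Col8a1, for example, runs from 15.2 to 104 CPM in sham and from 75.3 to 448 CPM after MI.

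A pair of lists, mitochondrial transcripts and immediate early and dissociation genes, moved in all 4 classes. RNA quality was not measured, and the cause was not tested. Mitochondrial transcripts were lower after MI in endothelial cells (median log2 -0.56, adjusted p = 0.00179), mural cells (-0.74, 1.37e-05), fibroblasts (-0.55, 0.00442) and monocytes or macrophages (-0.65, 0.0029), each lost at an adjusted p = 0.566 with an estimated correlation. On P1 day 3 their medians were 0.14, -0.19, 0.19 and 0.05, and on P8 day 1 -1.40, -1.40, -1.74 and -2.15. The sham library of P8 day 1 had the highest median mitochondrial share of all libraries, 10.1% against 3.11% in P8 MI day 1. Immediate early and dissociation genes were lower too (-0.68, -0.60, -0.52 and -0.33; adjusted p = 4.57e-09, 0.000134, 0.000654 and 0.000852; 0.566 in each with an estimated correlation), though not in monocytes or macrophages on P1 day 1 (0.06). On P8 day 1 their medians were -0.89 (endothelial), -0.57 (mural) and -0.89 (fibroblast), and the other pairs of these classes were below sham too. Jun and Dusp1, named after their values were seen, are among the genes outside the range of the other libraries in P8 MI day 1. Without the P8 day 1 pair the mitochondrial list had 0.0929 in endothelial cells, 0.305 in fibroblasts and 0.607 in monocytes or macrophages. Each kept its call after subtraction. Of the 76 tests of lists for MI, 34 passed, 24 up and 10 down, none with an estimated correlation (adjusted p = 0.458 to 0.872 with an estimated correlation), and 22 held after subtraction, where 3 had too few members left. The members passing numbered 33 higher and 3 lower over all genes, and 181 and 70 adjusted over the list alone. Secreted factors had a test direction opposite to their median and mean in endothelial cells (down, with a median of 0.10), and the median and the test of 1 or more unpassed lists also differed in sign in the other classes. On counts simulated at the depths of these libraries the MI fit found 91%, 94%, 93% and 87% of 4-fold changes in endothelial cells, mural cells, fibroblasts and monocytes or macrophages, and 46%, 30%, 27% and 25% of 2-fold changes, with 13, 4, 4 and 6 false calls. The simulation held no age or day effects and no free RNA, so real recovery may be lower.

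**Figure D4:**
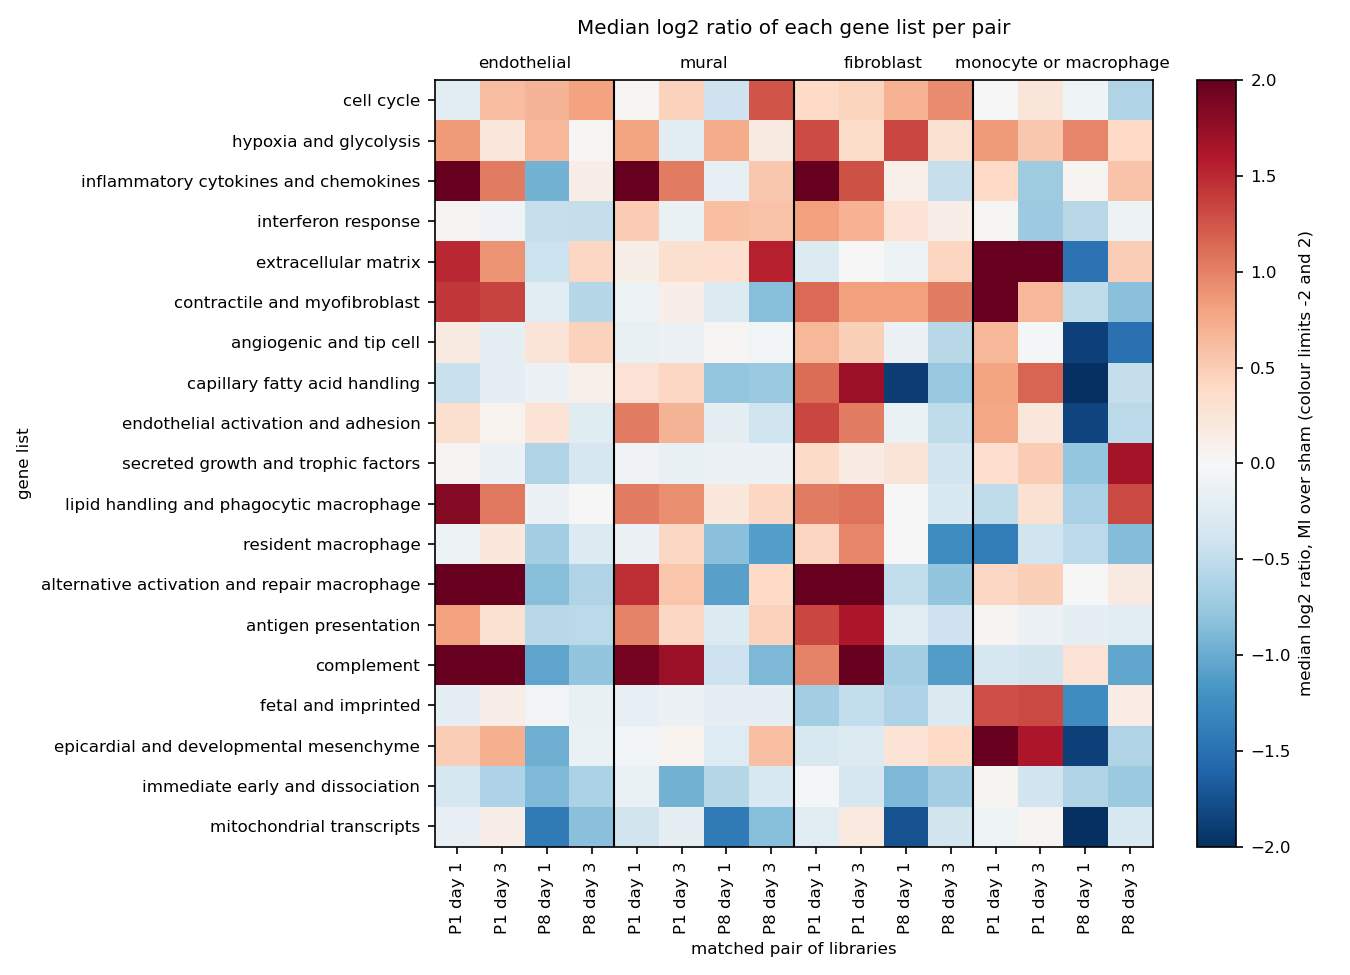
Median log2 ratio, MI over sham, of the members of each gene list (vertical axis) in each class and each of the 4 pairs of libraries (horizontal axis), as a colour with limits of -2 and 2. The contractile list in fibroblasts is up in all 4 pairs, with medians from 0.82 to 1.14.

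The libraries also compare hearts operated at P8 with hearts operated at P1, over both surgeries. Age and depth go together, since the P1 libraries held 16282672 to 31176495 total UMIs and the P8 libraries 3502948 to 13723246. With sums thinned to the smallest total, fewer fibroblast genes and no monocyte or macrophage gene passed for age. More endothelial genes did, and these counts are given below. In fibroblasts, Dlk1, an imprinted Notch ligand of fetal tissue, fell to 0.0421 of its P1 level (log2 -4.57 ± 0.33 SE, 8 libraries, adjusted p = 0.00106), from between 220 and 1163 CPM at P1 to between 16.8 and 44.0 CPM at P8. H19 (-2.19 ± 0.25, adjusted p = 0.00825) and Igf2 (to 0.25 of P1, 0.0214), both imprinted growth genes, and Fabp5 (-1.53 ± 0.27, 0.0396) fell with it. Pi16, a marker of adventitial fibroblasts, rose 7.46-fold (2.90 ± 0.26, adjusted p = 0.00226), and so did Wisp2 (3.21 ± 0.39, 0.00905), Pcolce2 (2.43 ± 0.18, 0.00106), an enhancer of procollagen processing, Serpina3n (2.34 ± 0.35, 0.0229) and Col8a1 (2.23 ± 0.20, 0.00226). Of 13078 genes, 60 were higher and 23 lower at P8, and 52 and 11 still passed after subtraction. Tnni1, the slow troponin I of the fetal heart, was lower in fibroblasts (-2.88 ± 0.45, 36.3% free RNA), mural cells (-2.70 ± 0.35, 31.5%) and endothelial cells (-2.43 ± 0.31, 23.8%).

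Mural cells had 85 genes higher and 34 lower at P8. Dlk1 (-3.87 ± 0.36, adjusted p = 0.00459), H19 (-2.86 ± 0.25, 0.00459) and Mest (-2.27 ± 0.34, 0.0275), another imprinted gene, fell, with Cpa1 (-3.30 ± 0.33, 0.00459), and Efhd1 (3.14 ± 0.55), Sncg (3.02 ± 0.45), Itih4 (2.80 ± 0.56), Pi15 (2.77 ± 0.54), Clu (2.62 ± 0.33) and Aldoart1 (2.58 ± 0.52) rose. Without cluster 31 of P8 MI day 1, which has Pi15 and Clu among its top genes, 78 were higher and 32 lower, Clu had 2.38 (adjusted p = 0.0272) and Pi15 2.12 (0.159). After subtraction 57 and 18 passed, without Mest (0.0561), Itih4 (0.0666), Pi15 (0.0673) and Aldoart1 (0.0523). Endothelial cells had 16 higher and 9 lower. AW112010, an interferon-responsive transcript annotated as a lincRNA, rose 10.3-fold (3.37 ± 0.24, adjusted p = 0.00507), with Ly6c1 (1.64 ± 0.21), Tmem255b (1.51 ± 0.17), Lims2 (1.45 ± 0.21), Sp100 (1.43 ± 0.20) and a gene listed only as ENSMUSG00000050936 (1.64 ± 0.19), and Gap43 (-1.95 ± 0.28) and Glipr2 (-1.97 ± 0.21; 61.3% free RNA) fell. Monocytes or macrophages had 1 gene, the chemokine Ccl5, which fell to 0.0388 of P1 (-4.69 ± 0.52, adjusted p = 0.0328), from between 150 and 280 CPM to between 0 and 11.3 CPM. Ccl4 in mural cells (-4.79) and Ccl3 in fibroblasts (-3.39) also passed, at 100% and 88.7% free RNA. Without 1 pair, at most 2 (endothelial), 6 (mural), 66 (fibroblast) and 3 (monocyte or macrophage) genes passed, the most without P8 day 1 in each class, and 0 in all classes without P1 day 1 (edgeR; the full fits had 2714, 1517, 1582 and 941 genes with an unadjusted p under 0.05 and DESeq2 called 554, 287, 348 and 150). Simulated 4-fold changes were found in 94%, 92%, 87% and 90% of cases and 2-fold changes in 42%, 25%, 34% and 19%.

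A further comparison tests whether the MI response itself differed between P1 and P8. In monocytes or macrophages, Mmp12, the macrophage elastase, was the 1 gene with a higher MI effect at P8 (adjusted p = 0.0338), at 557 and 431 CPM after MI on days 1 and 3 against 0 in both P8 shams. At P1 it had 97.0 and 165 CPM after MI against 131 and 222 CPM. Without TMM factors these P8 libraries had 552 CPM (138 counts) and 445 CPM (843 counts), at least 43.2-fold and 32.2-fold higher than their shams, taken at a floor of 3 counts per sham library. Free RNA gave 4.11% of Mmp12 counts, and its adjusted p after subtraction was 0.0756. Crip2 (-3.95 ± 0.47), known from vessel walls, and Hbb-bt (-4.91 ± 0.59), a haemoglobin, had a lower MI effect at P8, with 88.6% and 53.4% free RNA, and Mb (adjusted p = 0.0883) and Rbp7 (0.0913) did not pass.

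In endothelial cells 48 genes had a lower MI effect at P8 than at P1 and 0 a higher one (edgeR; 1040 with an unadjusted p under 0.05, DESeq2 160). Cd52 (-7.48 ± 1.01), Fcer1g (-6.46 ± 0.67), C1qa (-6.45 ± 0.58), Lyz2 (-6.19 ± 0.96) and Alox5ap (-6.06 ± 0.76), all genes of macrophages or other leukocytes, led them, each at 100% free RNA. C1qa had 49.8 and 93.4 CPM in the P1 MI libraries against 2.24 and 1.84 CPM in sham, and 2.16 and 3.39 against 7.61 and 5.73 CPM at P8. In fibroblasts 5 genes did so, among them the endothelial genes Fabp4 (-4.43 ± 0.50; 100%), Rbp7 (-6.44 ± 0.74; 98.0%) and Ctla2a (-4.65 ± 0.56; 83.9%). In mural cells 0 passed (edgeR; 681 with an unadjusted p under 0.05, DESeq2 39), and the smallest p-values were those of Rbp7 and Tyrobp (adjusted p = 0.0784) and of C1qa, Ctla2a and Lyz2 (0.14). After subtraction 0 genes passed in any class. Leaving out a pair leaves 1 MI and 1 sham library at that age. The counts of such fits cannot decide on an age difference and are not given. Whether the calls hold without a pair was therefore not shown.

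Of 76 tests of lists, 46 differed by age, 5 with a higher signed MI effect (log2) at P8 and 41 with a lower one, which can be a smaller rise or a larger fall. All 46, which include each list call by age below, were lost with an estimated correlation (adjusted p = 0.097 to 0.711 with an estimated correlation), and 12 held after subtraction, where 5 had too few members left. Cell cycle genes had the higher effect at P8 in endothelial cells (median 0.55, adjusted p = 2.78e-05; 0.464 with an estimated correlation) and fibroblasts (0.60, 0.00101; 0.435 with an estimated correlation), and both held after subtraction. Extracellular matrix genes did in mural cells (0.73, 0.0126), where fibroblast markers were high in P8 MI day 3 (6760 CPM against 1304 in sham), phagocytic macrophage genes in monocytes or macrophages (0.42, 0.0496) and epicardial genes in fibroblasts (0.61, 0.0115). With an estimated correlation these had an adjusted p of 0.696, 0.711 and 0.187, and after subtraction the first held (2.02e-11) and the others did not (0.864 and 0.118). Mitochondrial transcripts had a lower effect at P8 in all 4 classes (medians -1.18, -0.74, -1.08 and -1.20; adjusted p = 1.79e-06, 0.000152, 2.47e-06 and 2.41e-05; 0.304, 0.398, 0.304 and 0.406 with an estimated correlation), also after subtraction. In endothelial cells the list had medians of -0.17 and 0.14 in the P1 pairs and -1.40 and -0.83 in the P8 pairs (days 1 and 3), a larger fall at P8. Over all barcodes, the median mitochondrial share of the MI libraries was 3.01% and 3.89% at P1 and 3.11% and 3.05% at P8. In sham it was 4.35% and 3.88% at P1 and 10.1% and 5.91% at P8. The larger fall at P8 thus goes with high shares in the P8 shams. In fibroblasts the phagocytic list had an adjusted p of 2.94e-14 (camera). Other low p-values were those of complement in endothelial cells (median -3.92, 1.48e-26), extracellular matrix (-1.10, 1.97e-16), contractile (-2.25, 1.18e-15), antigen presentation (1.65e-12) and cytokines (6.72e-12) there, capillary fatty acid handling in fibroblasts (-3.30, 1.14e-23) and extracellular matrix (-1.93, 2.66e-16) in monocytes or macrophages. In the same order they had an adjusted p of 0.097, 0.161, 0.097, 0.097, 0.187, 0.097 and 0.154 with an estimated correlation. After subtraction the matrix list of endothelial cells turned and passed with a higher effect at P8 (adjusted p = 1.30e-06), and contractile genes (0.479) and cytokines (0.569) there and the matrix list of macrophages (0.733) turned without passing. By fibroblast markers alone the free RNA share of endothelial cells was 16.2% in P1 MI day 1 and 16.1% in P1 MI day 3. There 31.2% and 27.0% were subtracted, so the turn of matrix genes may come from subtracting too much. Antigen presentation in endothelial cells (0.0103) held its lower effect. So did contractile genes in mural cells (9.37e-05), phagocytic and immediate early genes in fibroblasts and alternative activation in monocytes or macrophages. Alternative activation had a lower effect at P8 in all 4 classes, cytokines, complement, antigen presentation and the phagocytic list in endothelial cells, mural cells and fibroblasts, and capillary fatty acid handling and endothelial activation in mural cells, fibroblasts and monocytes or macrophages. Lower effects at P8 were also found for angiogenic genes in fibroblasts and macrophages, for contractile genes in mural cells and macrophages, for resident macrophage genes in mural cells and fibroblasts, for fetal genes in macrophages, for epicardial genes in endothelial cells and macrophages, for immediate early genes in fibroblasts, and for interferon and secreted factor genes in endothelial cells, where the secreted factors had a mean of -0.60 but a median of 0.03. Of these, subtraction turned cytokines (adjusted p = 5.47e-05) and endothelial activation (0.0324) in mural cells and angiogenic genes in fibroblasts (0.00432), which then passed with a higher effect at P8. It also turned further lists without passing, such as the phagocytic list in mural cells (0.479) and antigen presentation in fibroblasts (0.149). Angiogenic genes of macrophages had medians of 0.67 and -0.04 at P1 and -1.86 and -1.49 at P8, contractile genes of mural cells -0.10 and 0.14 against -0.27 and -0.86, and immediate early genes of fibroblasts -0.02 and -0.34 against -0.89 and -0.67. Hypoxia and glycolysis did not pass in any class (lowest adjusted p = 0.4). Over all genes 0 members were higher and 19 lower, and adjusted over the list alone 10 and 144. Simulated 4-fold interactions were found in 26%, 19%, 19% and 7% of cases (endothelial, mural, fibroblast, monocyte or macrophage) and 2-fold ones in 3%, 1%, 1% and 0%.

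The last comparison asks whether the MI response differed between day 3 and day 1. In monocytes or macrophages the smallest p-values were those of Atp6v0d2 (log2 4.70 ± 0.59, adjusted p = 0.19), Spp1 (5.51 ± 0.89, 0.471), Gpnmb (6.02 ± 1.02, 0.48), Lpl (2.95 ± 0.57, 0.675) and the neutrophil gene S100a8 (-4.16 ± 0.63, 0.447). None of these passed. Spp1 had 12630 CPM in P1 MI day 3 and 19210 CPM in P8 MI day 3, against 1500 and 274 CPM in sham, while on day 1 it had 13530 and 8983 CPM after MI against 22820 and 24450 CPM in sham. The glycolytic enzyme Eno1 had -1.63 in endothelial cells (adjusted p = 1.0), -2.10 in mural cells (0.944) and -2.19 in fibroblasts (0.882), beside H2-Q6 (-2.50), H2-Q4 (-1.96), Nts (3.97) and Mt2 (-3.31). By edgeR 0 genes passed in all 4 classes, with 484, 462, 536 and 389 at an unadjusted p under 0.05 (endothelial, mural, fibroblast, monocyte or macrophage), and DESeq2 called 26, 1, 18 and 15. Fits without 1 pair hold 1 MI and 1 sham library on 1 of the days, so their counts are not given. Simulated 4-fold changes were found in 30%, 20%, 10% and 8% of cases and 2-fold ones in 3%, 0%, 0% and 0%.

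The leading genes lie at these places in GRCm38 (GENCODE vM21, start to end of the gene, protein coding unless stated). Col8a1 (ENSMUSG00000068196) is on chromosome 16 from 57624258 to 57754737, Timp1 (ENSMUSG00000001131) on X from 20870166 to 20874735 and Wisp2 (ENSMUSG00000027656) on 2 from 163820861 to 163833146. Tagln (ENSMUSG00000032085) is on 9 from 45929619 to 45936058, Clec3b (ENSMUSG00000025784) on 9 from 123150946 to 123157432 and Acta2 (ENSMUSG00000035783) on 19 from 34241090 to 34255590. Capg (ENSMUSG00000056737) is on 6 from 72544391 to 72562983, Tfpi2 (ENSMUSG00000029664) on 6 from 3962595 to 3988919 and Hpgd (ENSMUSG00000031613) on 8 from 56294585 to 56321043. Mmp12 (ENSMUSG00000049723) is on 9 from 7344381 to 7369499, Dlk1 (ENSMUSG00000040856) on 12 from 109452823 to 109463336, Pi16 (ENSMUSG00000024011) on 17 from 29317680 to 29330593 and Ccl5 (ENSMUSG00000035042) on 11 from 83525778 to 83530518. AW112010 (ENSMUSG00000075010) is a lincRNA on 19 from 11047612 to 11055808.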

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

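The tests on free RNA and depth behind the endothelial genes that differ by age, and the counts over other splits of the libraries, were chosen after the results were seen, and the tests on the library of P8 MI day 1 and on Xist and Y-linked genes were not.

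The MI effect differed between P1 and P8 for 48 genes in endothelial cells, 5 in fibroblasts and 3 in monocytes or macrophages, by the interaction test, and for 12, 11, 13 and 10 gene lists in endothelial cells, mural cells, fibroblasts and monocytes or macrophages, of which 0 were left with an estimated correlation (camera). The leading endothelial genes were Cd52 (log2 -7.48), Fcer1g (-6.46), C1qa (-6.45), Lyz2 (-6.19) and Alox5ap (-6.06), and 7 of the 48 stand on the macrophage or monocyte marker lists, 4 on the mural list and 3 on the fibroblast list. The free RNA estimate gave a median of 115% (quartiles 99.4 and 132) of the counts that 33 members outside the marker lists had in the P1 MI libraries, and after subtraction 0 genes passed. Only 15 members could still be tested, with a median of -3.13 (quartiles -5.25 and -1.41) against -3.73 (-4.24 and -2.97) for the same 15 before and -4.17 for all 48. Of these 15, 3 changed sign (Bgn from -3.03 to 2.20, Fhl1 from -2.73 to 5.54 and Myl9 from -3.85 to 5.36, named after their values were seen), so the median moved by less than the spread of the members and that spread became wider. The other 33 had too few counts left. In P1 MI days 1 and 3, macrophage markers alone gave endothelial cells a free RNA share of 29.2% and 28.3%. Fibroblast markers alone gave 16.2% and 16.1%, below the 31.2% and 27.0% that were subtracted. Fibroblast genes among the 48 may therefore have lost too many counts. Depth alone is argued against by the median of -4.34 with sums thinned to the smallest total, and RNA of other cells in the P1 MI libraries, which had 31.2% and 27.0% free RNA, may account for the members left with too few counts, and for the other 15 this stays open. An age difference of the endothelial response to MI stays open too and was not tested apart from it.

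In fibroblasts the age difference was -6.44 for Rbp7, -4.65 for Ctla2a and -4.43 for Fabp4, with Emcn and Rasip1 as the other members of the 5, named after their values were seen. In monocytes or macrophages it was 13.35 for Mmp12, a fitted value that is no bound because both P8 sham libraries hold 0 counts, -3.95 for Crip2 and -4.91 for Hbb-bt.

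Genes were counted where a library stood outside the range of the other 7 by more than 0.5 (log2, 10 CPM added). The library of P8 MI day 1 did so in all 4 tested classes at once for 152 genes, 9 higher and 143 lower. The other libraries had between 0 and 40. Scand1, for example, had 3.43 CPM in its endothelial cells against 218 CPM in P8 sham day 1, Nenf 23.1 against 204 CPM and Eif3f 115 against 1297 CPM (chosen after their values were seen). Depth and GC content are each argued against: 125 genes remained with thinned sums, and the median GC of the last 500 bases of the lower genes was 43.9% (95% of 10000 random lists matched on expression gave 42.1 to 45.9). In GENCODE vM21, 19.7% of the lower genes overlap another gene on the same strand (15.5 to 28.9). The libraries may have been counted with other gene models, so this value cannot decide on overlapping genes. A reference annotation other than that of the other libraries is a candidate explanation, since this library alone listed another number of genes, but it was not tested. A biological explanation was not tested either, since the library is the only 1 of its condition.

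The Y-linked gene Ddx3y fell after MI in endothelial cells (log2 -1.39, adjusted p = 0.0486, edgeR), mural cells (-2.73, 0.0151) and fibroblasts (-1.91, 0.00722), and had -1.82 without passing in monocytes or macrophages (0.188). Xist passed in none of the 4 classes, with 0.67 (0.114), 0.63 (0.15), 1.00 (0.0657) and 0.49 (0.444) in the same order. Among cells thinned to 2000 UMIs with a call by Xist or Y-linked genes, those called by Xist were 87.1% against 47.5% (P1 day 1), 87.4% against 41.1% (P1 day 3), 80.8% against 61.1% (P8 day 1) and 86.3% against 47.1% (P8 day 3), so the smallest difference was 19.7 points. The ratio of MI to sham of the Xist level in cells called by Xist had a median of 0.777. In the P8 pairs it was 1.05 and 0.889 (days 1 and 3), against 1.56 and 2.04 over all cells. This argues against a higher level of Xist per cell in the P8 pairs. In the P1 pairs the ratio was 0.563 and 0.665. Free Xist could add calls with few Xist UMIs there and lower the ratio, so the P1 pairs cannot decide. After subtraction 101% of the log2 change was left. Subtraction takes a like share from any gene at a similar level in all classes, so it cannot decide on free RNA. Whether free Xist raised the calls by Xist in the P1 MI libraries stays open. A higher share of female pups in all 4 MI libraries may account for this pattern, and every comparison of MI with sham then also compares more female with fewer female cells. The labels give no sex, so what stays open could not be tested.

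Splitting the 8 libraries in other ways into 4 and 4, 33 splits in all, gave fewer MI genes than the real split in mural cells (40 genes, at most 12 in another, 1 of 33 as large) and fibroblasts (164, at most 99, 1 of 33). The real counts include Y-linked genes. Chance is not excluded by this, since most of these splits leave a matched pair on 1 side. Only 8 of them part all 4 matched pairs, too few for a share under 0.05, with at most 1 mural and 24 fibroblast genes in another, and without the P1 day 1 or the P1 day 3 pair 0 genes passed in both classes (edgeR; 1620 mural and 2510 fibroblast genes had an unadjusted p under 0.05 in the full fit and DESeq2 called 161 and 569). In endothelial cells (8, at most 31, 2 of 33) and monocytes or macrophages (7, at most 23, 3 of 33) other splits gave more genes, so chance is not excluded there either. The highest other split of the first 3 classes put both P1 MI libraries with both P8 day 3 libraries, and of monocytes or macrophages with P8 sham day 1 and P8 MI day 3, which points to a structure of the samples around the P1 MI libraries. For age the real counts of 25, 119, 83 and 1 (endothelial, mural, fibroblast, monocyte or macrophage) were the largest of the 33 splits, the highest others being 2, 0, 2 and 0, so 1 of 33 was as large in each.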

How the results depend on the processing

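The tests with free RNA subtracted, with P1 or P8 libraries alone, with an unnamed cluster added and with a mural cluster left out were chosen after the results were seen, and all other alternatives before. Counts of genes are in the order endothelial, mural, fibroblast, monocyte or macrophage where 4 are given. Of 204 counts of genes under all alternatives, 85 stayed within 1.5 times, 57 were larger and 62 smaller, and of 21 values of class shares with a call in the full fit 6 kept it and 15 lost it, while of 63 without a call 58 stayed so in the same direction and 5 changed direction. Of 286 values of lists with a call 144 kept it, 118 lost it and 24 changed sign, and of 308 without a call 212 stayed so, 37 gained it, 56 changed direction without passing and 3 with passing. No call of a named gene changed sign. In the counts by setting below, a call whose gene had no value under a setting is left out and not counted as lost. This is why 89 and not 106 calls are given for free RNA subtraction. The counts with the unnamed cluster and without the mural cluster each cover 1 class. By setting, calls of named genes kept numbered 99 of 103 with DESeq2, 99 of 106 with RLE factors, 106 of 106 without filter, 85 of 106 with at most 10% mitochondrial UMIs, 94 of 106 without doublet removal, 58 of 93 with thinned sums, 50 of 89 with free RNA subtracted, 17 of 20 with the unnamed cluster and 21 of 27 without the mural cluster of P8 MI day 1. For MI they were 33 of 61 with each age and day as a block, 0 of 61 without age and day terms, 54 of 61 at Leiden resolution 0.5, 60 of 60 with P1 libraries alone and 0 of 44 with P8 libraries alone. Without the P1 day 1, P1 day 3, P8 day 1 and P8 day 3 pair they were 0 of 95, 1 of 96, 72 of 105 and 15 of 106, in fits with fewer libraries. Depth limits the monocytes or macrophages most, with 217066 counts in P8 sham day 3. The cause of a change was not tested unless it follows from fewer libraries or counts.

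DESeq2 gave 198, 161, 569 and 46 genes for MI, 554, 287, 348 and 150 for age, 160, 39, 131 and 59 for age by MI and 26, 1, 18 and 15 for day by MI. Without a count filter edgeR gave 92, 460, 623 and 246 for MI, 449, 653, 446 and 575 for age, 346, 184, 268 and 138 for age by MI, and 81, 62 and 72 for day by MI in mural cells, fibroblasts and monocytes or macrophages. With at most 10% mitochondrial UMIs MI gave 0 genes in endothelial cells, 15 in mural cells and 4 in monocytes or macrophages, and age 38 in the last, and the class shares (log2) were 2.36 for dendritic, 2.72 for epicardial cells and 1.39 for monocytes or macrophages. TMM factors on class counts gave 2.60 for epicardial cells and 1.49 for monocytes or macrophages. Without doublet removal, age gave 92 endothelial and 82 monocyte or macrophage genes, and age by MI 3 in fibroblasts and 1 in monocytes or macrophages. Thinned sums gave 0 endothelial, 9 fibroblast and 0 monocyte or macrophage genes for MI, 74, 22 and 0 for age, and 2 mural genes for age by MI. The fit with each age and day, and so each matched pair, as a block gave 1 endothelial, 12 mural and 87 fibroblast genes for MI, no age and day terms gave 0, 0, 0 and 0, and Leiden resolution 0.5 gave 0 in endothelial cells. P1 libraries alone gave 1008, 527, 1389 and 635 and P8 libraries alone 0, 0, 0 and 0, in fits with few degrees of freedom. With the unnamed cluster age gave 62 endothelial genes, and without the mural cluster of P8 MI day 1 MI gave 25 mural genes.

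With free RNA subtracted, MI gave 7 mural, 43 fibroblast and 1 monocyte or macrophage genes, age 151 endothelial and 11 monocyte or macrophage genes, and age by MI 0 endothelial, 0 fibroblast and 0 monocyte or macrophage genes. An estimated correlation left 0 lists for MI and 0 for age by MI, and subtraction 18 for age by MI. Of the lists that passed before or after it, subtraction turned these for MI, each with its adjusted p there: cytokines in endothelial (0.655) and mural cells (0.888), extracellular matrix in endothelial cells (0.517), and in fibroblasts the phagocytic (0.653), resident macrophage (0.0344), antigen presentation (0.203) and complement (9.69e-06) lists. For age by MI it turned, in endothelial cells, cytokines (0.569), extracellular matrix (1.30e-06), contractile (0.479), secreted factors (0.569), alternative activation (0.929) and epicardial genes (0.982), and in mural cells cytokines (5.47e-05), capillary fatty acid handling (0.433), endothelial activation (0.0324), the phagocytic list (0.479), resident macrophage (0.499) and antigen presentation (0.117). It also turned cytokines (0.916), angiogenic genes (0.00432) and antigen presentation (0.149) in fibroblasts, and extracellular matrix (0.733), contractile (0.531), endothelial activation (0.471) and fetal genes (0.433) in monocytes or macrophages. Matrix genes of endothelial cells may have been subtracted too much in P1 MI days 1 and 3. Fibroblast markers alone gave shares of 16.2% and 16.1% there, where 31.2% and 27.0% were taken off.

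Leaving out 1 pair at a time, MI gave 0 to 0, 0 to 58, 0 to 389 and 0 to 39 genes, age 0 to 2, 0 to 6, 0 to 66 and 0 to 3, age by MI 0 to 553, 0 to 325, 0 to 628 and 0 to 270, and day by MI 0 to 169, 0 to 102, 0 to 298 and 0 to 0, all by edgeR, with the unadjusted and DESeq2 counts given above for the full fits. Log2 changes of class shares ran from -1.84 to -0.79 (B cells), 0.06 to 1.17 (cardiomyocytes), 2.30 to 2.68 (dendritic), 0.69 to 0.98 (endocardial), -0.94 to -0.47 (endothelial), 1.68 to 2.82 (epicardial), -0.37 to 0.73 (erythroid), 0.08 to 0.65 (fibroblasts), 1.14 to 1.76 (monocytes or macrophages), -0.69 to -0.22 (mural), -0.13 to 0.98 (neutrophils) and -0.81 to 0.79 (unnamed). Lists for MI that passed numbered 25 to 44. The capillary fatty acid list of monocytes or macrophages had adjusted p from 0.0144, without the P8 day 1 pair and then up, to 0.568.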

Other observations

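The genes below were named by rules fixed before the values were seen unless stated, and no test of an explanation was chosen after the result was seen in this part.

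In single settings, where 1 library stands against 1 and there is no test, the largest ratios of monocytes or macrophages on P8 day 3 included these. Spp1, osteopontin, had 19844 CPM (95% Poisson interval 19644 to 20046) against 286 CPM (219 to 366) in sham, Gpnmb, a lysosomal glycoprotein, 625 (590 to 662) against 13.8 (2.85 to 40.4), and Fabp5, a fatty acid binding protein, 2992 (2914 to 3071) against 129 (85.7 to 186). On P8 day 1 the same class had Mmp13, a collagenase, at 276 CPM (215 to 350) against 4.27 (0.108 to 23.8), Mmp12 at 552 (464 to 653) against 0 counts, and Gpnmb lower, with 5 counts against 101 counts, or 431 CPM (351 to 524), in sham. On P1 day 3 Arg1 was at 241 CPM (227 to 256) against 16.9 (9.64 to 27.4), and Gpnmb at 719 against 105. Fibroblasts of P8 MI day 3 had Col11a1, a fibrillar collagen, at 194 CPM (182 to 206) against 9.25 (3.00 to 21.6), and Ctgf, a matricellular growth factor, at 383 (367 to 400) against 44.4 (28.4 to 66.1). Endothelial cells of P8 MI day 3 had Plvap, of fenestrated and sprouting vessels, at 219 CPM (203 to 236) against 23.8 (15.9 to 34.2), and Lrg1, an angiogenic secreted glycoprotein, at 149 (136 to 163) against 28.7. In fibroblasts of P8 MI day 1, the metallothionein Mt2 had 1576 CPM against 118.

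Epicardial cells, a class with enough cells for values only at P1, had higher Cxcl2, a neutrophil chemokine, after MI, at 2802 CPM against 71.4 on day 1 and 465 against 55.5 on day 3, where the free RNA estimate alone gave 2971 and 549 CPM after MI. Tagln in them was at 158 CPM against 0 counts and at 122 against 5.84, with 122 and 82.9 CPM from free RNA. C3, the central complement component, was at 311 CPM against 3790 and at 1795 against 5150, the water channel Aqp1 at 64.9 against 602 and 378 against 1142, and the interferon-induced Gbp2 at 20.9 against 253 and 118 against 356. Endocardial cells, the inner lining, had Angpt2, a vessel-remodelling ligand, at 29.3 CPM against 164 on P1 day 1 and 17.8 against 75.4 on day 3. Each compares 1 library with 1, and the P1 MI libraries had 31.2% and 27.0% free RNA.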
